A study of Homo sapiens with 9 samples.

How the data were processed

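The series holds 9 arrays of human pulmonary artery endothelial cells in 3 groups of 3: siRNA against ACTN4 (siACTN4), siRNA against HLA-DPA1 (siHLADPA1) and negative control siRNA (siNC). Per the labels' protocols, commercial primary cells were grown in endothelial growth medium and treated with Silencer Select siRNA. Total RNA was extracted with Trizol, and biotinylated cRNA was hybridised to Affymetrix Clariom S Human arrays. The authors processed the arrays with the Transcriptome Analysis Console, per the submitters' processing notes, and deposited 1 table of gene-level log2 signals with 1 column per array. The labels used here name no software version, summarisation method, siRNA sequence, transfection time or origin of the replicates. The log base was read from the values, which ran from 1.60 to 19.14 over gene features. Between 143 and 157 gene features per array lay above 16, the ceiling of a 16-bit scanner, so a transform that stretches the scale is probably in the values, and every log2 difference and fold is on that deposited scale. The quartiles of the 9 arrays were nearly equal, so no further normalization was applied.

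The table held 24351 features, of which 21448 were gene features and the others controls: 2197 positive, 612 negative, 63 ERCC, 23 background and 8 spike or labelling features. Of the gene features, 17709 had exactly 1 symbol in the probe table provided, 0 had several, and 3739 were unnamed here and were tested but not named. All 17709 gene identifiers matched the RefSeq table (used for names only), and 0 symbols were updated. The named features held 17687 distinct symbols. To keep personal traits of the cell donor out of the text, 77 features were tested but kept out of written tables and figures. No coordinates are given, because the labels name no genome build.

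Groups and numbers were read from the sample titles, and no array was left out. The 3 comparisons were siACTN4 with siNC, siHLADPA1 with siNC, and siACTN4 with siHLADPA1. All 9 arrays were fitted together with limma (lmFit and eBayes, without a block, 6 residual degrees of freedom), and the moderated test of limma was used, two-sided. P-values were adjusted by Benjamini-Hochberg over the 21448 gene features, and a feature with adjusted p under 0.05 was called changed. Where a count is adjusted over a list alone, the adjustment covered only that list's members. A feature was taken as non-overlapping when all 3 values of 1 group lay above or below all 3 of the other, which chance gives in 10% of features. Background was the 95th percentile of the 612 negative control features on each array, and a group was at background for a gene when none of its arrays passed that level. No background filter was applied before testing. The median residual SD was 0.245 and the prior degrees of freedom 5.41.

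The comparisons, the thresholds, the rule for named genes, 32 gene lists and all alternatives but 1 were written before the data were examined. The rule named the targeted genes, the 8 largest increases and the 8 largest decreases from siNC among called genes with a symbol and non-overlapping values, the 5 largest of each sign between the siRNAs, and up to 3 called members of each list with the largest change. It also named the 5 genes of each direction changed most by both siRNAs and the 3 of each kind changed in opposite directions. Genes outside the rule are marked as chosen after their values were seen. The lists had 1015 distinct members, of which 937 were measured. They covered antigen presentation, interferon and NF-kB responses, vasoactive and pulmonary hypertension genes, BMP, TGF-beta and Notch signalling, cell cycle, p53 and apoptosis, actin and SRF or YAP/TAZ targets, endothelial and mesenchymal genes, hypoxia, respiration, stress responses, cholesterol, immediate early genes, haemostasis, matrix, RNA sensing and 5 checks of other cell types. Each list was tested with limma's camera at its preset correlation of 0.01, with 1 feature per symbol (the highest mean), at least 5 measured members, the targeted genes left out, and adjustment over the 32 lists. Each list was also tested with a correlation estimated from the residuals, where camera also uses only the 6 residual degrees of freedom, and with fry. Camera tests a list against the other genes, so a called list may hold members that did not change.

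Because both comparisons with siNC share its arrays, overlap and correlation were compared with 100 simulations that kept the 9 arrays' residual spread and the shared arrays but held no siRNA effect, and with the overlap of independent lists. The pipeline was tested on simulated data: in 10 runs with 200 changed features, 73.4% of features changed by log2 1 and 99.9% of those changed by log2 2 were recovered, 0 with the wrong sign, and 6.53% of calls were false. A list shifted by 0.5 was called in 10 of 10 runs, and 2 of 310 tests of other lists were called. Both kinds of simulation drew each gene independently, so they do not give the error rate for lists whose members are correlated.

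The alternatives were a replicate block from the numbers in the titles, a fit of only the groups compared, quantile normalization, median centring, leaving out the dimmest features, eBayes with trend and robust settings, array weights, 1 feature per symbol, other thresholds, each array left out in turn, and for lists the estimated correlation and fry. A filter on background was added after the data were seen. The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.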

Results

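Human pulmonary artery endothelial cells received an siRNA against ACTN4, which encodes the actin crosslinker alpha-actinin-4, an siRNA against HLA-DPA1, which encodes the alpha chain of the MHC class II molecule HLA-DP, or a negative control siRNA (siNC). Each group held 3 arrays, 9 in all, and this number limits the precision of every value. The labels do not say whether the 3 arrays of a group came from separate cultures, so each p-value measures the spread between these samples, which may be technical. Gene features had medians of 5.48 to 5.53 on the deposited log2 scale, and arrays correlated at 0.992 to 0.993 within groups and at 0.983 to 0.987 between groups. On each array, background was taken as the 95th percentile of the negative control features, and 36.7% to 43.4% of the gene features lay above it. Where 1 of the groups compared lay at background, the fold is given as at least the distance to that floor, or to the gene's own value if higher. All folds are on the deposited scale.

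ACTN4 fell by 5.94 on the log2 scale with siACTN4 (SE 0.195, 3 arrays against 3, limma adjusted p = 5.79e-08), which left 1.62% of the siNC level on the deposited scale. With siACTN4 it lay between the 97.1 and 97.7 percentiles of the negative controls, still above background. Its level was 13.66, 13.89 and 13.93 on the siNC arrays, 8.24, 7.47 and 7.94 on the siACTN4 arrays, and 14.35, 14.42 and 14.50 on the siHLADPA1 arrays. With siHLADPA1, ACTN4 differed from siNC by 0.59 (adjusted p = 0.0880, not called, and adjusted p = 0.0107 over the 2 targeted genes alone). HLA-DPA1 read 5.21, 6.25 and 6.09 with siNC, 5.34, 4.27 and 4.56 with siACTN4, and 3.32, 3.79 and 4.24 with siHLADPA1. The HLA-DPA1 feature thus lay below background on all 9 arrays, between the 85.5 and 93.3 percentiles of the negative controls with siNC and between the 44.3 and 69.4 percentiles with siHLADPA1. Its signal was lower with siHLADPA1 (log2 difference -2.07, SE 0.34, adjusted p = 0.00256), but a level below background gives no measure of how much HLA-DPA1 transcript was removed. With siACTN4 the HLA-DPA1 difference was -1.13 (adjusted p = 0.04995), the arrays of the groups overlapped, and the call was lost under several alternatives, for example at adjusted p = 0.0635 with only the 6 arrays of these groups in the fit.

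**Figure D1:**
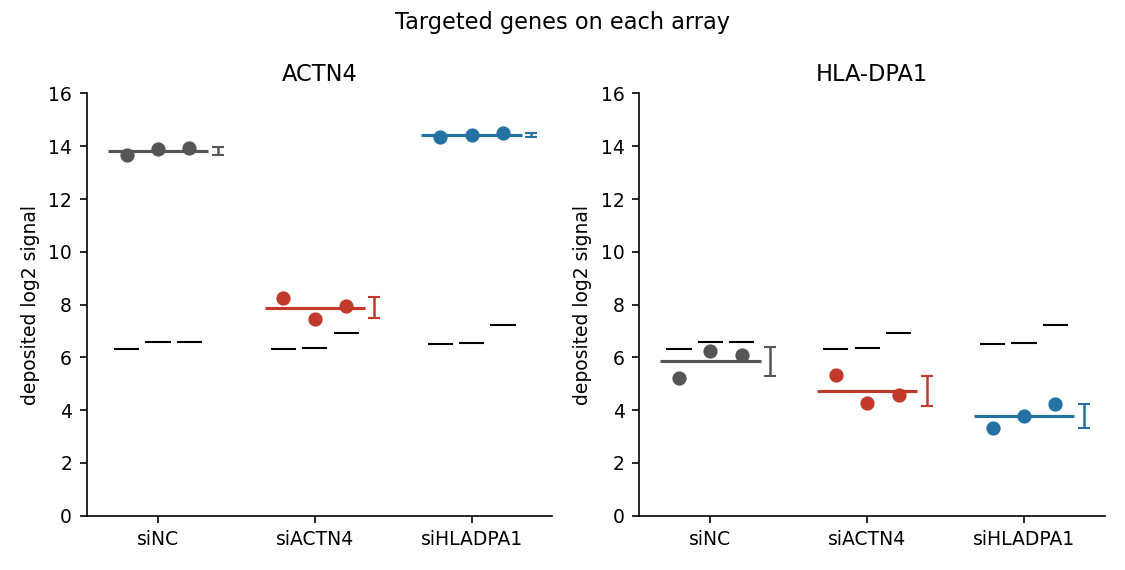
Deposited log2 signal of ACTN4 (left) and HLA-DPA1 (right) on each of the 9 arrays by siRNA group, with the group mean, an SD bar and, as short dashes, the 95th percentile of the negative control features of each array. ACTN4 averaged 13.83 with siNC and 7.89 with siACTN4, whereas HLA-DPA1 lay below background on every array.

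With siACTN4, CLDN1, which encodes the tight junction protein claudin-1, rose from background to at least 51.7-fold above it (log2 difference 6.90, SE 0.29, 3 arrays against 3, adjusted p = 4.66e-07). CD69, a leukocyte activation receptor, rose at least 10.6-fold (log2 difference 5.21, SE 0.23), and the antiviral gene RSAD2 rose by 4.35 (SE 0.55, adjusted p = 0.000345). SERPIND1, which encodes the thrombin inhibitor heparin cofactor II, rose by 3.90 (SE 0.22), the adhesion gene CEACAM1 by 3.56 (SE 0.18) and the interferon-induced gene IFIT3 by 3.24 (SE 0.44). The complement receptor gene C3AR1 rose at least 2.13-fold and CLIC3 at least 4.15-fold. Among genes with a symbol, the largest decreases after ACTN4 itself were in KLRG1, an inhibitory lectin receptor (-3.28, SE 0.32), the LIM domain-binding gene LDB2 (-3.17, SE 0.17), the sideroflexin gene SFXN3 (-3.11, SE 0.23) and CPA3, which fell to background, at least 2.90-fold. KLRG1 averaged 5.93 with siACTN4, under the background level of each array in that group (6.33 to 6.94), so the size and rank of its decrease are uncertain. PDE7B, a cAMP phosphodiesterase gene, changed by -3.00 (SE 0.18), the heparan sulfate sulfatase gene SULF1 by -2.98 (SE 0.16) and PRR11 by -2.85 (SE 0.17). Of 21448 features, 2726 changed (1430 higher and 1296 lower, 12.7%), 1002 of them at least 2-fold (485 higher and 517 lower), and the median size of the changes was 0.87. The 3 siACTN4 values lay entirely above or below the 3 siNC values in 29.2% of all features, against 10% by chance, and 248 of the changed features were at background in both groups.

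Cell cycle genes were lower with siACTN4. Of 52 genes of G2/M and mitosis, 20 fell and 2 rose (27 and 2 when adjusted over the list alone), with a median of -0.48 (camera adjusted p = 7.14e-11). Among them were the kinase gene MELK (-1.62, SE 0.21), the proliferation marker MKI67 (-1.61, SE 0.19) and the spindle gene NUSAP1 (-1.37, SE 0.19). Of 48 genes of G1/S and DNA replication, 14 fell and 0 rose (24 and 1 when adjusted over the list alone), with a median of -0.53 (adjusted p = 2.84e-09). The decreases included ORC6, at background in both groups, E2F8 (-1.19, SE 0.22) and the thymidylate synthase gene TYMS (-0.99, SE 0.15). The p53 targets did not pass as a list (4 rose and 2 fell of 33, 4 and 3 when adjusted over the list alone, median -0.14, adjusted p = 0.427). Of its members, TP53INP1 (-1.78) and TRIM22 (-1.42) fell and PMAIP1 rose (1.46). Apoptosis regulators also changed both ways (8 higher and 6 lower of 37, 8 and 7 when adjusted over the list alone, median -0.0036, adjusted p = 0.871). Lower genes included TNFSF10, a death ligand gene (-2.35), BAD (-1.86) and the cytochrome c gene CYCS (-1.65). BAD averaged 6.30 with siACTN4, just under the background level of each array in that group.

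Of the endothelial identity genes, 17 of 54 fell and 3 rose (20 and 6 when adjusted over the list alone), with a median of -0.27 (adjusted p = 8.88e-05). VWF, the von Willebrand factor gene, fell by 2.53 (SE 0.19) and the endomucin gene EMCN changed by -2.21 (SE 0.19), and the tight junction gene OCLN fell to background, at least 2.92-fold. The 3 that rose, named after their values were seen, were TEK (0.94), NOS3 (0.78) and ETS2 (0.68). Vasoactive genes were lower as a list (7 fell and 3 rose of 31, 12 and 3 when adjusted over the list alone, median -0.26, adjusted p = 0.00366). This call was lost at adjusted p = 0.235 with an estimated correlation. Among them CALCRL, the receptor gene for adrenomedullin and CGRP, fell by 2.44, its partner RAMP2 fell at least 1.96-fold, and the serotonin receptor gene HTR1B fell by 1.15. Mesenchymal genes of endothelial-mesenchymal transition did not pass (5 rose and 4 fell of 31, 9 and 4 when adjusted over the list alone, median 0.14, adjusted p = 0.211). SNAI1 (2.33) and TAGLN (2.13) rose and POSTN (-1.92) fell. The extracellular matrix list was lower (11 fell and 8 rose of 62, 12 and 8 when adjusted over the list alone, median -0.15, adjusted p = 0.0299; adjusted p = 0.131 with an estimated correlation). MGP (-2.63), SPOCK1 (-2.30) and BGN (-2.12) were the most changed. The matrix call was also lost with the dimmest features left out (0.0773), with features at background left out (0.0618), without siNC replicate 2 (0.0573) and without siACTN4 replicate 1 (0.0627).

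Actin cytoskeleton and focal adhesion genes, tested without ACTN4, were higher with siACTN4: 22 of 72 rose and 4 fell (36 and 8 when adjusted over the list alone), with a median of 0.39 (adjusted p = 9.22e-06). The integrin gene ITGA3 rose by 1.27 (SE 0.16), whereas MYH10, a non-muscle myosin heavy chain gene, fell by 1.47 (SE 0.17). SRF and YAP/TAZ targets did not pass (5 rose and 3 fell of 33, 10 and 4 when adjusted over the list alone, median 0.14, adjusted p = 0.102). TEAD1 rose (1.52) and IGFBP3 fell (-1.16). NRF2 and oxidative stress genes were higher (19 rose and 2 fell of 31, 22 and 2 when adjusted over the list alone, median 0.61, adjusted p = 7.14e-10). They were led by OSGIN1 (1.81), the cystine transporter gene SLC7A11 (1.66) and SRXN1, at least 1.18-fold. Hypoxia and glycolysis genes were higher (14 rose and 2 fell of 40, the same when adjusted over the list alone, median 0.37, adjusted p = 3.81e-05). ANGPTL4 rose at least 2.18-fold, BHLHE40 by 1.96 and VEGFA by 1.81. The unfolded protein and integrated stress response list was higher (13 rose and 4 fell of 42, 17 and 4 when adjusted over the list alone, median 0.41, adjusted p = 4.16e-05; adjusted p = 0.0973 with an estimated correlation). The asparagine synthetase gene ASNS rose by 1.63 and SLC3A2 by 1.52. Cholesterol genes were higher (10 rose and 2 fell of 28, 12 and 2 when adjusted over the list alone, median 0.32, adjusted p = 0.00137; adjusted p = 0.205 with an estimated correlation). STARD4 (1.23) and ABCA1, at least 1.35-fold, rose, although ELOVL6 fell by 1.45.

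Of the type I interferon response, 28 of 41 genes rose and 1 fell with siACTN4 (35 and 1 when adjusted over the list alone), with a median of 1.13 (adjusted p = 1.94e-16; adjusted p = 0.196 with an estimated correlation). IFIT1 was among them (3.10, SE 0.37). Interferon gamma genes were higher (6 rose and 1 fell of 22, 8 and 1 when adjusted over the list alone, median 0.32, adjusted p = 0.00128; adjusted p = 0.131 with an estimated correlation). GBP1 rose by 1.77, and CXCL10 was called at background in both groups. The member that fell, TNFSF10 (-2.35), had the largest change of the list. NF-kB and endothelial activation genes were higher (11 rose and 4 fell of 38, 17 and 4 when adjusted over the list alone, median 0.39, adjusted p = 0.00123). The adhesion molecule gene ICAM1 rose by 2.26 (SE 0.20), TNFRSF9 at least 1.80-fold and the chemokine gene CCL5 at least 1.41-fold. MHC class I genes were higher (2 rose of 17, 7 when adjusted over the list alone, median 0.47, adjusted p = 0.00142; adjusted p = 0.235 with an estimated correlation). The called members were the peptide transporter gene TAP1 (1.05) and NLRC5, at background in both groups, a call lost under 7 alternatives with adjusted p up to 0.138. The MHC class II list did not pass, with 12 of 18 members at background in both groups (1 rose and 2 fell of 18, the same when adjusted over the list alone, median -0.0285, adjusted p = 0.871). Within it, the lysosomal protease gene CTSL rose by 2.32 (SE 0.14) and RFX5, a regulator of class II transcription, fell by 0.97. Immediate early genes were higher (10 rose and 1 fell of 33, 10 and 2 when adjusted over the list alone, median 0.25, adjusted p = 0.0069; adjusted p = 0.176 with an estimated correlation). The phosphatase genes DUSP1 (2.33) and DUSP5 (1.73) rose and DUSP6 (-1.26) fell. With features at background left out, the NF-kB and immediate early lists were no longer called (both at adjusted p = 0.0618).

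The remaining lists did not pass with siACTN4. The pulmonary arterial hypertension genes gave 1 higher and 3 lower of 23, the same when adjusted over the list alone (median -0.15, adjusted p = 0.146). ATP13A3 rose (1.63), and ACVRL1, a BMP receptor gene (-1.09), and SMAD1 (-0.71) fell. The BMP signalling list changed both ways (7 higher and 5 lower of 31, 8 and 7 when adjusted over the list alone, median 0.18, adjusted p = 0.223). ID2 was at 2.17, the transferrin receptor gene TFRC at 1.67 and BMP4 at -1.88. The TGF-beta response gave 10 higher and 2 lower of 24, 11 and 4 when adjusted over the list alone (median 0.18, adjusted p = 0.0563), with TGFBI at 1.82 and the receptor gene TGFBR2 at -1.87. Notch genes (3 higher and 5 lower of 27, 3 and 6 when adjusted over the list alone, median -0.15, adjusted p = 0.126) included lower EFNB2 (-1.02) and GJA5, at least 2.23-fold, and higher NOTCH2 (1.38). The respiratory chain gave 0 higher and 3 lower of 40, 0 and 0 when adjusted over the list alone (median 0.0251, adjusted p = 0.79). These were NDUFV2 (-0.70), COX7C (-0.58) and TFAM (-0.51), calls lost under 4, 7 and 13 alternatives. Haemostasis genes gave 8 higher and 6 lower of 24, 10 and 6 when adjusted over the list alone (median 0.22, adjusted p = 0.13), with PLAUR at 2.08. RNA interference and double-stranded RNA sensing genes gave 7 higher and 2 lower of 24, 9 and 2 when adjusted over the list alone (median 0.11, adjusted p = 0.0804), with IFIH1 at 1.58, DICER1 at 1.30 and TLR3 at 1.30. Among the cell type checks, whose members lay mostly at background in both groups, adjusted p was 0.747 for smooth muscle and pericyte genes, 0.766 for fibroblast, 0.148 for lymphatic endothelium, 0.587 for epithelium and 0.79 for leukocyte genes, each with at most 1 member higher and 1 lower. Single members of these checks still changed, such as the macrophage-associated gene CD68 (1.83) and MMRN1 (-1.49), from the lymphatic check. MMRN1 is also on the endothelial identity and haemostasis lists and was bright, averaging 16.6 with siNC.

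With siHLADPA1, interferon-induced genes led the increases over siNC: RSAD2 rose by 5.60 (SE 0.55, 3 arrays against 3, adjusted p = 9.40e-05), IFIT3 by 4.43 (SE 0.44), the nucleotide kinase gene CMPK2 by 4.30 (SE 0.36), IFIT1 by 3.88 (SE 0.37) and MX2 by 3.28 (SE 0.54). The chemokine gene CXCL10 rose at least 1.52-fold, CXCL8 by 2.81 (SE 0.20) and the actin-binding gene TAGLN by 2.92 (SE 0.16). The largest decreases were in IL6ST, which encodes the shared receptor subunit gp130 (-3.79, SE 0.18, adjusted p = 1.30e-06), and RRBP1, a ribosome receptor of the endoplasmic reticulum, which fell to background, at least 11.1-fold. The transcription factor gene GTF3A (-3.26, SE 0.17), the KDEL receptor gene KDELR1 (-3.15, SE 0.13), the mitochondrial DNA-binding gene SSBP1 (-3.12, SE 0.21), the endoplasmic reticulum chaperone gene HYOU1 (-3.12, SE 0.14), SDF4 (-3.06, SE 0.17) and LDB2 (-2.96, SE 0.17) followed. Of 21448 features, 1987 changed (1007 higher and 980 lower, 9.26%), 695 of them at least 2-fold (276 higher and 419 lower), with a median size of 0.87. The 3 siHLADPA1 values lay entirely above or below the 3 siNC values in 26.8% of all features, against 10% by chance, and 186 of the changed features were at background in both groups. Without siHLADPA1 replicate 2 the count was 1317, of which 604 were higher, and the higher count was 619 without siNC replicate 1 and 633 without siHLADPA1 replicate 3.

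Mitotic genes showed the broadest decrease with siHLADPA1: 40 of 52 genes of G2/M and mitosis fell and 0 rose (50 and 0 when adjusted over the list alone), with a median of -1.03 (adjusted p = 1.65e-33). The kinesin gene KIF14 fell to background, at least 1.19-fold, as did KIF15, at least 1.06-fold, and the kinetochore gene CENPF fell by 1.54 (SE 0.22). Of 48 genes of G1/S and DNA replication, 17 fell and 2 rose (26 and 2 when adjusted over the list alone), with a median of -0.56 (adjusted p = 1.56e-12). Among the decreases were the checkpoint gene CLSPN (-1.68), UHRF1 (-1.57) and E2F8 (-1.55). The cyclin gene CCND1, also on the SRF and YAP/TAZ list, was 1 of the 2 that rose (1.22). The p53 targets were higher (8 rose and 0 fell of 33, 10 and 0 when adjusted over the list alone, median 0.38, adjusted p = 3.01e-05). GADD45A rose by 1.38, SESN2 by 1.04 and the translesion polymerase gene POLH by 1.00. Apoptosis regulators did not pass as a list (5 higher and 4 lower of 37, 7 and 4 when adjusted over the list alone, median 0.06, adjusted p = 0.504), with BAK1 at 1.54 and CASP4 at -1.22.

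The unfolded protein and integrated stress response list was lower with siHLADPA1 (13 fell and 3 rose of 42, 16 and 5 when adjusted over the list alone, median -0.13, adjusted p = 0.000495; adjusted p = 0.119 with an estimated correlation). After HYOU1, the list's decreases included PHGDH, which fell to background, and MANF (-1.17, SE 0.16). SRF and YAP/TAZ targets were higher (12 rose and 0 fell of 33, 17 and 1 when adjusted over the list alone, median 0.39, adjusted p = 4.04e-07). TEAD1 rose by 1.69 and the cyclin gene CCND1 by 1.22. Actin cytoskeleton and focal adhesion genes were higher (15 rose and 5 fell of 73, 21 and 6 when adjusted over the list alone, median 0.25, adjusted p = 0.000973; adjusted p = 0.0824 with an estimated correlation). The myosin light chain gene MYL9 rose by 1.90, although the integrin gene ITGB5 changed by -2.73 (SE 0.15) and CAPZA1 by -1.53. Endothelial identity genes were lower (13 fell and 0 rose of 54, 17 and 0 when adjusted over the list alone, median -0.31, adjusted p = 3.15e-08). Decreases included VWF (-1.95, SE 0.19), the beta-catenin gene CTNNB1 (-1.45) and CD34 (-1.33). The matrix list was lower (8 fell and 1 rose of 62, 14 and 2 when adjusted over the list alone, median -0.12, adjusted p = 0.00194; adjusted p = 0.0548 with an estimated correlation). NID1 changed by -1.35 and MMP2 by -1.34. Vasoactive genes were lower (7 fell and 1 rose of 31, the same when adjusted over the list alone, median -0.17, adjusted p = 0.00167; adjusted p = 0.231 with an estimated correlation). The cyclooxygenase gene PTGS1 changed by -1.66 and the apelin gene APLN by -1.51.

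The type I interferon list rose most broadly: 34 of 41 genes rose and 0 fell with siHLADPA1 (38 and 0 when adjusted over the list alone), with a median of 1.48 (adjusted p = 1.34e-29; adjusted p = 0.107 with an estimated correlation). Interferon gamma genes were higher (7 rose and 1 fell of 22, 11 and 1 when adjusted over the list alone, median 0.39, adjusted p = 8.89e-05; adjusted p = 0.0809 with an estimated correlation). GBP1 rose by 1.84, and the member that fell was TNFSF10 (-1.21). NF-kB and endothelial activation genes were higher (10 rose and 2 fell of 38, 17 and 3 when adjusted over the list alone, median 0.38, adjusted p = 0.000105). TNFAIP3, which restrains NF-kB signalling, rose by 1.89 and CCL5 at least 1.33-fold. Immediate early genes were higher (6 rose and 0 fell of 33, 10 and 1 when adjusted over the list alone, median 0.28, adjusted p = 0.00167; adjusted p = 0.119 with an estimated correlation). DUSP5 (2.71), DUSP1 (2.49) and SPRY4, at least 2.19-fold, rose. NRF2 and oxidative stress genes were higher (9 rose and 2 fell of 31, 10 and 2 when adjusted over the list alone, median 0.24, adjusted p = 0.00406; adjusted p = 0.231 with an estimated correlation). The heme oxygenase gene HMOX1 rose by 1.63 and GPX3 by 1.40, and NOX4 fell at least 1.67-fold. The NRF2 call was lost with features at background left out (adjusted p = 0.0691). The MHC class II list, tested without HLA-DPA1, did not pass, with 11 of 17 members at background in both groups (1 rose and 1 fell of 17, 1 and 2 when adjusted over the list alone, median 0.0181, adjusted p = 0.693). HLA-DPB1, which encodes the partner chain, fell by 0.80 (SE 0.20, adjusted p = 0.0296), a call lost under 6 alternatives with adjusted p up to 0.107. The member that rose was CTSL (0.54, adjusted p = 0.0345), a call lost under 8 alternatives. MHC class I genes did not pass (3 rose and 2 fell of 17, 3 and 3 when adjusted over the list alone, median 0.0398, adjusted p = 0.849). The immunoproteasome gene PSMB9 rose by 1.37 and TAP1 by 1.33.

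The other lists did not pass with siHLADPA1. The pulmonary arterial hypertension genes gave 1 higher and 3 lower of 23, 2 and 3 when adjusted over the list alone (median -0.11, adjusted p = 0.483), with PDGFD lowered to background, SMAD1 at -1.54 and ATP13A3 at 1.09. BMP signalling gave 5 higher and 2 lower of 31, 7 and 2 when adjusted over the list alone (median -0.0287, adjusted p = 0.91), with BMP4 at -1.48 and ID2 at 1.36. The TGF-beta response gave 4 higher and 3 lower of 24, 6 and 3 when adjusted over the list alone (median -0.11, adjusted p = 0.849), with INHBA at 1.05. Mesenchymal genes gave 3 higher and 5 lower of 31, 3 and 6 when adjusted over the list alone (median -0.16, adjusted p = 0.0756), with CDH11 at -1.71. Notch genes gave 3 higher and 2 lower of 27, the same when adjusted over the list alone (median -0.20, adjusted p = 0.394), with EFNB2 at -1.85 and the Notch ligand gene JAG1 at 1.18. Hypoxia and glycolysis genes gave 6 higher and 2 lower of 40, 7 and 4 when adjusted over the list alone (median 0.10, adjusted p = 0.211), with the glucose transporter gene SLC2A3 at 1.82. In the respiratory chain 1 of 40 genes fell, COX7C (-1.35), with a list median of 0.11 (adjusted p = 0.211). Cholesterol genes gave 7 higher and 1 lower of 28, the same when adjusted over the list alone (median 0.17, adjusted p = 0.0674), with MVD at 1.42. Haemostasis genes gave 2 higher and 5 lower of 24, the same when adjusted over the list alone (median 0.0096, adjusted p = 0.324), with SERPIND1 at 1.32 and ENTPD1 at least 1.51-fold lower. RNA interference and RNA sensing genes gave 6 higher and 3 lower of 24, 7 and 4 when adjusted over the list alone (median 0.13, adjusted p = 0.122), with the RNA sensor RIGI at 2.08, DROSHA at -1.86 and AGO1 at -1.59. The cell type checks, again mostly at background, had adjusted p of 0.874 for smooth muscle and pericyte, 0.84 for fibroblast, 0.0647 for lymphatic endothelium, 0.564 for epithelium and 0.84 for leukocyte genes, each with at most 1 member changed. The leukocyte member was CD68, at 1.58.

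**Figure D2:**
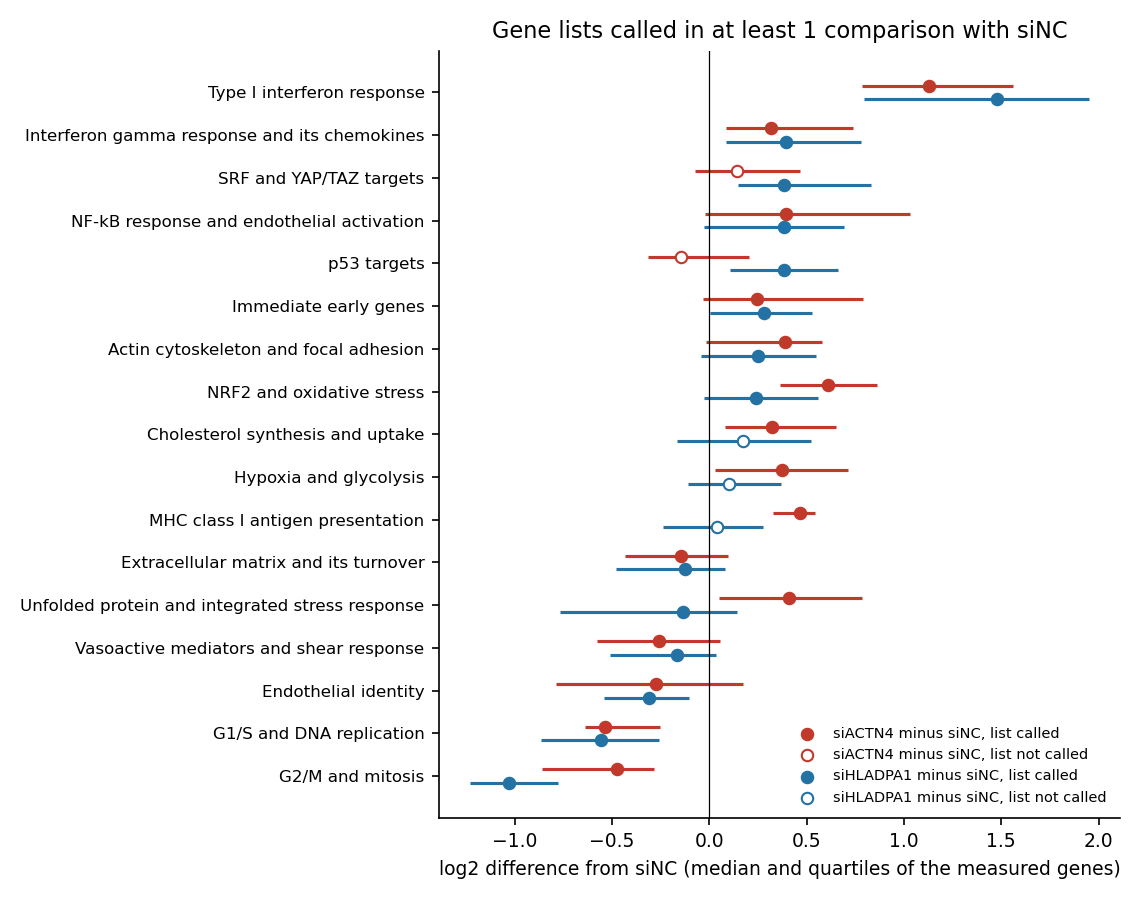
Median log2 difference from siNC with its quartiles over the members of each of the 17 lists called with at least 1 siRNA, for siACTN4 and siHLADPA1 (3 arrays per group), with filled symbols for called lists. The type I interferon medians were 1.13 and 1.48, and the G2/M medians were -0.48 and -1.03.

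Measured directly against each other, the siRNAs separated CLDN1 most among genes with a symbol other than ACTN4: it was higher by 4.46 with siACTN4 than with siHLADPA1 (SE 0.29, 3 arrays against 3, adjusted p = 4.18e-06). RRBP1 was at least 13.0-fold higher with siACTN4, KDELR1 higher by 3.74 (SE 0.13), the channel gene PANX1 by 3.65 (SE 0.24) and CD69 at least 8.92-fold. ACTN4 was lower with siACTN4 (-6.54, SE 0.195), as were SFXN3 (-3.98, SE 0.23), CXCL8 (-3.04, SE 0.20), the cytochrome b5 gene CYB5B (-2.83, SE 0.17) and PXK (-2.67, SE 0.16). The HLA-DPA1 difference between the siRNAs was not called over all features (0.94, SE 0.34, adjusted p = 0.106, and adjusted p = 0.0168 over the 2 targeted genes alone), with both groups below background. In all, 2490 features differed (1261 higher and 1229 lower with siACTN4, 11.6%), 896 of them at least 2-fold (469 higher and 427 lower), with a median size of 0.87. The values did not overlap in 28.4% of all features, against 10% by chance, and 258 of the features that differed were at background in both groups.

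The unfolded protein and integrated stress response list differed most between the siRNAs, with 22 of 42 genes higher and 2 lower with siACTN4 (24 and 3 when adjusted over the list alone, median 0.79, adjusted p = 1.87e-12). HYOU1 (2.48) and SLC7A11 (1.63), chosen after their values were seen, were among the genes higher with siACTN4. G2/M genes were higher with siACTN4 than with siHLADPA1 (18 higher and 0 lower of 52, 21 and 1 when adjusted over the list alone, median 0.49, adjusted p = 6.1e-08; adjusted p = 0.0838 with an estimated correlation). The p53 targets were lower (11 lower and 1 higher of 33, 15 and 2 when adjusted over the list alone, median -0.38, adjusted p = 1.56e-05). SRF and YAP/TAZ targets were lower (9 lower and 1 higher of 33, 11 and 3 when adjusted over the list alone, median -0.24, adjusted p = 0.00259; adjusted p = 0.0564 with an estimated correlation). Hypoxia and glycolysis genes were higher (13 higher and 5 lower of 40, 14 and 5 when adjusted over the list alone, median 0.25, adjusted p = 0.00259; adjusted p = 0.0564 with an estimated correlation). NRF2 genes were higher (10 higher and 1 lower of 31, 14 and 2 when adjusted over the list alone, median 0.36, adjusted p = 0.00322; adjusted p = 0.398 with an estimated correlation). Type I interferon genes were lower with siACTN4 than with siHLADPA1 (8 lower and 1 higher of 41, 10 and 1 when adjusted over the list alone, median -0.42, adjusted p = 0.00154). The interferon call was lost with an estimated correlation (adjusted p = 0.819) and with fry (adjusted p = 0.234). Mesenchymal genes were higher with siACTN4 (8 higher and 3 lower of 31, 10 and 4 when adjusted over the list alone, median 0.24, adjusted p = 0.0167; adjusted p = 0.191 with an estimated correlation). So were MHC class I genes (5 higher and 0 lower of 17, 8 and 1 when adjusted over the list alone, median 0.52, adjusted p = 0.0175; adjusted p = 0.676 with an estimated correlation) and haemostasis genes (6 higher and 2 lower of 24, 9 and 4 when adjusted over the list alone, median 0.27, adjusted p = 0.0291; adjusted p = 0.147 with an estimated correlation). These last 3 calls were also lost with features at background left out, at adjusted p = 0.191, 0.191 and 0.22. The MHC class I call was also lost without siACTN4 replicate 2 (0.0787) or siHLADPA1 replicate 3 (0.054), and the mesenchymal call without siHLADPA1 replicate 2 (0.051). With the dimmest features left out, the MHC class I (0.0785) and haemostasis (0.0808) calls were lost too. CALR (0.87), named after its values were seen, was among the 5 higher MHC class I genes and is also on the unfolded protein list. The other 22 of 32 lists did not pass, with adjusted p from 0.124 (TGF-beta response) to 0.984 (epithelium check), MHC class II among them (adjusted p = 0.665).

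**Figure D3:**
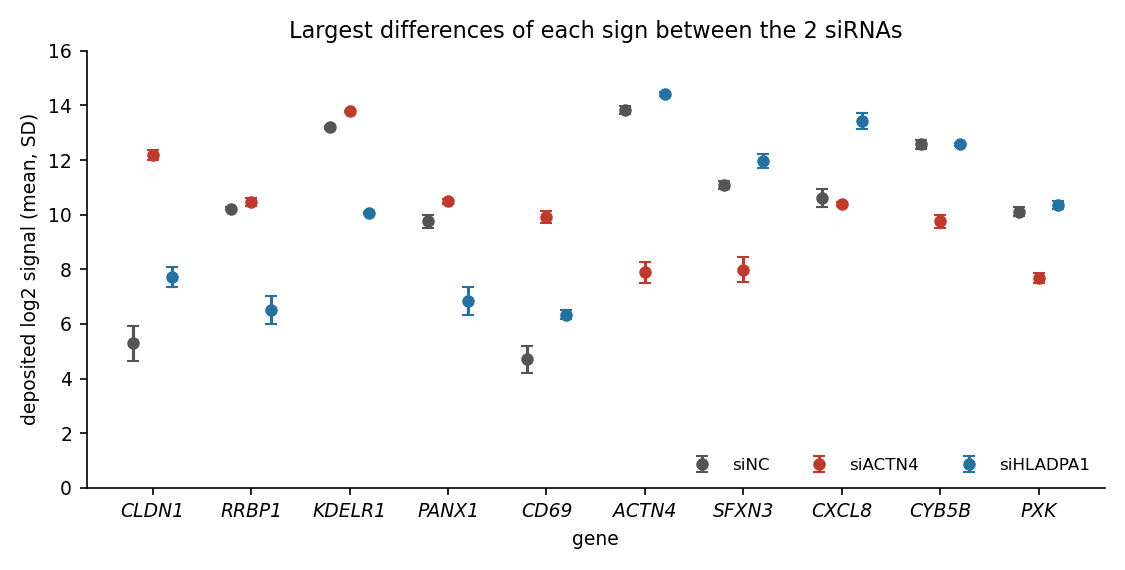
Mean and SD of the deposited log2 signal in each group (3 arrays each) for the 5 genes with the largest positive and the 5 with the largest negative difference between the siRNAs. RRBP1 and KDELR1 were low with siHLADPA1 only, and ACTN4 and SFXN3 were low with siACTN4 only.

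RSAD2, IFIT3, IFIT1, CLIC3 and CLDN1 rose with both siRNAs, CLIC3 at least 4.15-fold with siACTN4 and 2.44-fold with siHLADPA1, and CLDN1 at least 51.7-fold and 2.34-fold. LDB2 fell with both (-3.17 and -2.96), as did the histone genes H1-5 (-2.48 and -2.49) and H2BC14 (-2.21 and -2.37), the carboxypeptidase inhibitor gene LXN (-2.11 and -2.49) and the chemokine receptor gene ACKR3, at least 1.52-fold and 1.31-fold. Of 984 features called with both siRNAs, 894 had the same direction (495 higher and 399 lower) and 90 opposite directions. MAPK6 (1.57 and -1.89), NETO2 (1.42 and -1.47) and the retinoic acid receptor gene RARB (1.52, and at least 1.14-fold lower) rose with siACTN4 and fell with siHLADPA1. NCR3LG1 fell at least 1.42-fold with siACTN4, a call lost under 4 alternatives, and rose by 1.45 with siHLADPA1. STEAP2 fell between groups at background with siACTN4 and rose at least 1.23-fold with siHLADPA1, calls lost under 8 and 6 alternatives. SFXN3 fell by 3.11 and rose by 0.87, the last a call lost under 6 alternatives with adjusted p up to 0.12. Of the 894 same-direction features, 195 still differed between the siRNAs, and of the 1742 called with siACTN4 only, 974 differed, as did 543 of the 1003 called with siHLADPA1 only.

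Both comparisons used the same 3 siNC arrays, which by itself makes the differences correlate. Independent lists of these sizes would share 126.4 features in the same direction and 126.2 in opposite directions, against 894 and 90 observed. In 100 simulations with no siRNA effect, at most 2 features were called with siACTN4 and 1 with siHLADPA1, and 0 with both, so these simulations give no reference for the overlap. The differences correlated at r = 0.492 across features (Spearman 0.458), which are not independent replicates, and the simulations gave 0.484 to 0.516. Shared controls with no effect hold r near 0.5 by design, so r does not measure a shared effect. Their covariance was 0.104, against 0.0218 to 0.0235 in the simulations. The 3 siNC arrays cannot be split into separate control sets of at least 2, so part of the overlap may come from the shared controls.

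**Figure D4:**
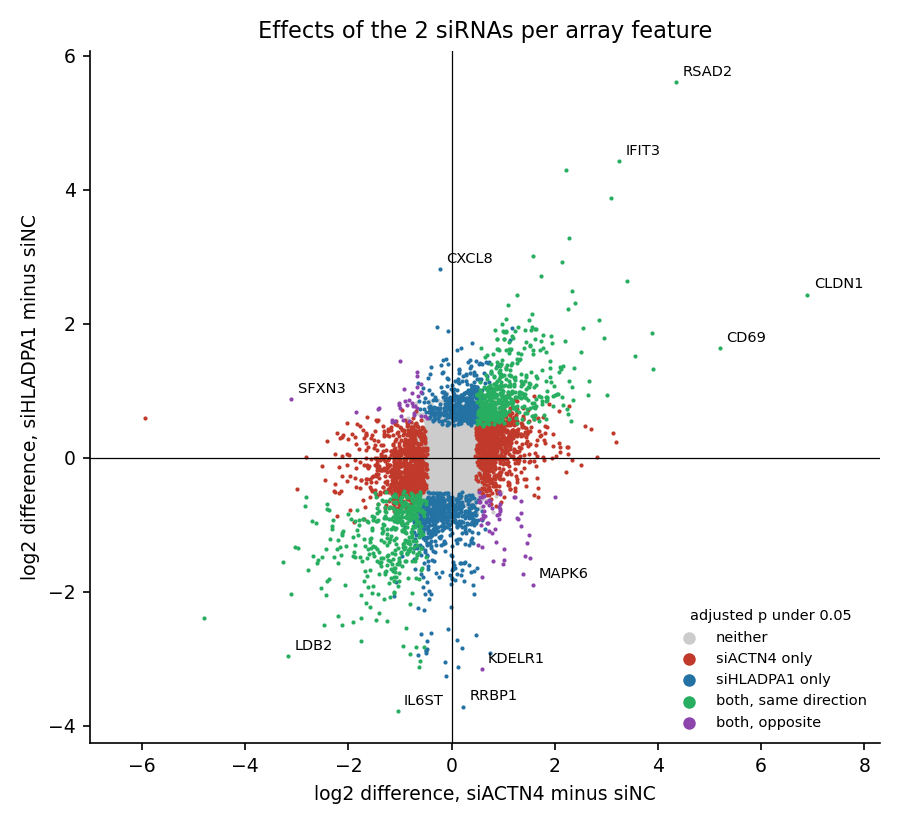
Log2 difference from siNC with siHLADPA1 against that with siACTN4 for each feature (3 arrays per group), coloured by which comparisons called it, with 77 features left out of the drawing. Of 984 features called in both, 894 had equal signs, among them RSAD2 and LDB2, and 90 opposite signs.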

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

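With 3 arrays per group and only 36.7% to 43.4% of the gene features above background on each array, small changes in dim genes could not be resolved. Called results kept their direction: 0 reversed under any alternative. Some lists called in neither test had opposite directions with camera and fry, such as the MHC class II list with siACTN4 (adjusted p = 0.871 and 0.144). Outside the arrays left out, tests of named genes kept their call in 1603 cases, lost it in 18, gained it in 1 and were called in neither fit in 32. For lists these counts were 355, 35, 22 and 524. With 1 array left out in turn they were 1763, 82, 0 and 45 for named genes, and 346, 5, 9 and 504 for lists. A group left with 2 arrays borrowed its spread from the others.

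With a 2-fold minimum beside the adjusted p, the counts were 1002 with siACTN4, 695 with siHLADPA1 and 896 between the siRNAs. With unadjusted p and 2-fold they were 1012, 699 and 904, and at adjusted p under 0.01 they were 1454, 959 and 1277, all by construction of the threshold. The filter on background, chosen after the data were seen, gave 3011 features with siHLADPA1 and 1517 changed in the same direction by both. eBayes with trend and robust settings gave 1377 in the same direction. The cause was not tested for either. Lists called fell to 7, 6 and 2 with the estimated correlation, so the other list calls depend on the preset setting. The estimated setting also lowers the degrees of freedom of the camera test to the 6 residual ones. A lost call therefore need not come from correlated members. With fry, which tests a list without comparing it with other genes, 24 lists were called for siACTN4.

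ACTN4 with siHLADPA1 (0.5934) became called with trend and robust settings (adjusted p = 0.00726), with the background filter (0.0215) and without siACTN4 replicate 2 (0.0435), and ran from 0.5105 to 0.6459 with 1 array left out. HLA-DPA1 with siACTN4 lost its call with only the groups compared (-1.125, 0.0635), quantile normalization (-1.119, 0.0545), median centring (-1.109, 0.0540) and array weights (-1.07, 0.0607). It ran from -1.445 to -0.8987 with 1 array left out, and lost its call without siNC replicate 2 (0.164) or 3 (0.149), siACTN4 replicate 2 (0.170) or 3 (0.139), or siHLADPA1 replicate 2 (0.0691). The cause was not tested. Under the background filter HLA-DPA1 was not among the features tested. Each target had 1 feature, so no alternative over several features of a gene was run.

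With 1 array left out, the counts ran from 1970 to 2580 with siACTN4, from 1317 (without siHLADPA1 replicate 2) to 1852 with siHLADPA1, from 1755 to 2431 between the siRNAs and from 608 to 723 in the same direction. These fits had fewer arrays, which by itself lowers counts.

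The numbers 1 to 3 in the titles gave no sign of pairing the samples: residual correlations of same-numbered arrays ran from -0.0817 to 0.0121, and 0 of 9 arrays matched best with their own number. With these numbers as a replicate block, 2324, 1642 and 2127 features were called in the 3 comparisons and 726 in the same direction, and HLA-DPA1 with siACTN4 (-1.125) had adjusted p = 0.0759.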

Other observations

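The gene families and the chaperone subset below, and the tests of RNA sensing, of separate off-target silencing of chaperone transcripts and of fewer cells in S phase, were chosen only after the results were seen. Among 327 families of 8 to 150 genes grouped by symbol, the histone cluster genes changed most. Apart from the histones, a family held every symbol with the same root before its first digit, so it can include genes of other function. With siACTN4, 33 of 64 fell and 0 rose (median -0.78, camera adjusted p = 1.41e-20; adjusted p = 0.0191 with an estimated correlation), and with siHLADPA1, 48 fell and 0 rose (median -1.22, adjusted p = 9.58e-41; adjusted p = 0.00278 with an estimated correlation). H4C3 fell by 1.76 and 2.39 and H4C14 by 1.19 and 2.07 with siACTN4 and siHLADPA1. The family includes some members outside the replication-dependent clusters' usual set, such as H1-10 and H1-8, and near-identical copies whose probes may read one another, so the genes are not independent. The MCM family, which holds the MCM helicase genes, was also lower with both. Of 11 genes, 4 fell with siACTN4 (median -0.52, adjusted p = 0.032) and 5 with siHLADPA1 (median -0.66, adjusted p = 0.000363). Both calls were lost with an estimated correlation (adjusted p = 0.933 and 0.327). The metallothioneins were higher with both (6 of 13 rose, median 0.44, adjusted p = 0.000632, and 9 rose, median 0.65, adjusted p = 8.8e-08), but not at adjusted p = 0.933 and 0.475 with an estimated correlation.

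Other families were called with 1 siRNA only, which by itself shows no difference between the siRNAs. With siACTN4, the RPL and RPS families, which hold the ribosomal protein genes, were lower. In RPL 7 of 34 fell (median -0.29, adjusted p = 0.00123), and in RPS 6 of 32 fell and 3 rose (median -0.32, adjusted p = 0.0287). Proteasome subunits (PSMB median 0.46, adjusted p = 0.0176, and PSMD median 0.35, adjusted p = 0.0362) and beta-tubulins (4 of 8 rose, median 0.60, adjusted p = 0.0176) were higher. All 5 calls were lost, each at adjusted p = 0.933 with an estimated correlation. With siHLADPA1, CXCL chemokines (5 of 14 rose, median 0.31, adjusted p = 0.00497), DUSP phosphatases (7 of 23 rose, median 0.34, adjusted p = 0.00114), IFI genes (4 of 8 rose, median 0.62, adjusted p = 0.00442) and VPS sorting genes (7 of 35 rose, median 0.31, adjusted p = 0.0112) were higher and kinesins lower (12 of 40 fell, median -0.18, adjusted p = 0.0243). These calls were lost too, at adjusted p = 0.593, 0.327, 0.593, 0.475 and 0.601 with an estimated correlation. With siACTN4, where they were not called, 8 of 23 DUSP genes were higher and 1 lower (median 0.21, adjusted p = 0.27), 3 of 8 IFI genes were higher (median 0.62, adjusted p = 0.19) and 4 of 40 kinesins were lower (median -0.15, adjusted p = 0.508). The siACTN4 medians were -0.0307 for CXCL (1 higher and 1 lower) and 0.0333 for VPS (4 higher and 2 lower). Families called only with siACTN4 had siHLADPA1 medians of -0.0946 (RPL), -0.082 (RPS), 0.191 (PSMB), 0.141 (PSMD) and 0.0367 (beta-tubulins). Between the siRNAs, only the histones (12 higher with siACTN4, median 0.38, adjusted p = 9.14e-06), beta-tubulins (median 0.79, adjusted p = 0.0141) and CXCL chemokines (median -0.26, adjusted p = 0.0141) differed. These 3 calls were lost as well (adjusted p = 0.452, 1 and 1 with an estimated correlation).

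Replication-dependent histone transcripts accumulate in S phase, so fewer cells in S phase could lower them with both siRNAs. That hypothesis requires the G1/S list to fall in both comparisons. The smaller of its 2 median decreases was -0.534, but this was known beforehand, so it lends the hypothesis no support. It also cannot separate fewer S-phase cells from lower expression per cell, since no cell cycle measurement accompanies the arrays.

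Type I interferon genes were higher with both siRNAs than with siNC, list calls lost at adjusted p = 0.196 and 0.107 with an estimated correlation. A single array did not account for this: the list median kept at least 0.773 of its value without any 1 array, although siNC replicate 1 read lowest (-0.562 against the siNC mean) and leaving it out gave the lowest medians (0.875 and 1.22). Further normalization between arrays moved the medians by at most 0.0556. The deposited arrays already had nearly equal quartiles, so this check could hardly move them and does not test the submitters' own processing. The siNC cells also received an siRNA, so RNA sensing common to all 3 groups would cancel in both comparisons. Only stronger sensing of both targeting siRNAs than of siNC could raise the same genes whichever gene is targeted. The 2 effects had r = 0.84 over list members, a value that the shared siNC arrays raise by themselves. Each gene had 1 siRNA group. Such a difference in sensing, a property of the siNC arrays and a shared consequence of losing either gene therefore all stay open.

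Of 12 endoplasmic reticulum chaperone genes, 8 fell with siHLADPA1 (median -0.82), among them HSPA5 (-0.94) and CRELD2 (-0.96), and 10 of 12 were higher with siACTN4 than with siHLADPA1. With siACTN4 the chaperone genes were higher as a set (2 rose and 1 fell, median 0.37, camera adjusted p = 0.0426, and 0.0824 with an estimated correlation). The amino acid and integrated stress genes of the same list were not called with siHLADPA1 (median -0.0278, adjusted p = 0.774). They too were higher with siACTN4 than with siHLADPA1 (11 of 27 higher and 2 lower, median 0.49, adjusted p = 3.1e-06, and 0.0729 with an estimated correlation). ATF6, XBP1 and ERN1 were in neither part. The difference of the chaperone genes between the siRNAs kept at least 0.963 of its median without any 1 array, so no single array accounts for it. The median siNC level of the chaperone genes was 4.66 log2 units above background, so dim signal does not account for the set. However, SDF2L1, which was not called, lay below background on average. Of the chaperone genes 66.7% fell, against 4.90% of all named genes, but the genes were singled out because they fell, so this share decides nothing about separate direct silencing of each transcript. Off-target effects, on each transcript or on a shared regulator, stay open, and because HLA-DPA1 lay below background on every array, the data cannot tie the decrease to loss of HLA-DPA1.

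The effects of the siRNAs correlated over genes (0.492, jackknife SE 0.0631), but shared siNC arrays with no effect hold this value near 0.5 by design, so it decides nothing. The covariance was 4.41 times the highest simulated value, which shared noise in the siNC arrays did not give in the simulations. A property of the siNC arrays beyond the simulated noise could add to it and stays untested.

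The 6 arrays of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each comparison 1 of 10 splits, the real one, gave as many changed features (2726, 1987 and 2490), and the highest count of any other split was 0. Every other split puts arrays of both groups on each side, so real differences enter its spread. A low count is then likely in any case, and the 0 is no reference for the real counts.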
